A study of Mus musculus with 2 samples.

How the data were processed

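Single-cell RNA sequencing was run on live CD45+ single cells sorted from livers that carried metastases of B16F10, a mouse melanoma line. There was 1 library from WT mice and 1 from Vsig4 knockout (Vsig4 KO) mice, and the labels do not say how many mice each library pooled. The labels name the 10x Genomics 5′ chemistry with feature barcoding and V(D)J libraries; only gene expression is analysed here. Per the submitters' processing notes, reads were aligned and counted with Cell Ranger 7.1.0 on mm10. The deposited matrices held UMI counts per gene and barcode, as whole numbers, for 31253 genes in both libraries. Of these genes, 31107 were matched by gene identifier to GENCODE M21, from which positions were taken.

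The WT library held 6929 barcodes with 28537154 UMIs and the Vsig4 KO library 5799 barcodes with 25119175 UMIs. No barcode held fewer than 500 UMIs. Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were used, which left 6872 WT and 5746 Vsig4 KO barcodes. Doublets were scored with scrublet as run by scanpy 1.11.5 in each library. Its own threshold marked 4 WT cells (0.058%) and 14 Vsig4 KO cells (0.244%), so it did not work on these libraries. The highest scores were removed instead, at 0.8% per 1000 barcodes, which took out 381 WT and 267 Vsig4 KO cells. In all, 6491 WT cells (93.7% of barcodes) and 5479 Vsig4 KO cells (94.5%) were kept, with 26270949 and 23400037 UMIs.

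Both libraries were clustered together without batch correction: 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and leiden clustering at resolution 1.5. Vsig4, sex-linked, receptor-segment, mitochondrial, ribosomal protein, haemoglobin and stress genes were kept out of the variable genes. Clusters were named from markers of 29 cell classes that were fixed before the data were examined. The scoring thresholds for a name, and the rule of taking the clustering with the highest modularity of 200 random starts, were set after the data had been seen. Earlier clusterings from a single start were looked at first; in the first of them the macrophage lists had other values than here, so 200 other starts were run as an alternative. A cluster stayed unnamed when fewer than 3 of its markers were detected, when another class led its top 10 genes, or when 2 classes scored alike. Unnamed clusters held 6.01% of WT and 4.05% of Vsig4 KO cells. Macrophage-like cells were clustered once more to look for Kupffer cells, a step added after the data had been seen.

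UMIs were summed per library and class in classes with at least 50 cells in each library and scaled to CPM, in which every class sum has the same total. A ratio is Vsig4 KO over WT. Cells are not replicates, and with 1 library per genotype no test was run and no p-value is given. Shares carry Clopper-Pearson intervals, CPM values exact Poisson intervals and ratios exact conditional binomial intervals, all at 95%. The interval of a list's median comes from Poisson draws around the sums. These intervals cover counting error only, not the differences between mice, sorts or libraries. Where a gene had 0 UMIs in 1 genotype, the fold was taken against a floor of 3 counts over the group, without the counting error of the other genotype.

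There were 34 gene lists fixed before the data were examined: cytotoxic effector, checkpoint and exhaustion, naive and memory, T cell activation, CD5 and TCR signalling, tissue residency, regulatory T cell, proliferation, type I interferon response, interferon-gamma response, MHC class II, MHC class I, costimulatory ligands, coinhibitory ligands and suppressive factors, inflammatory cytokines and chemokines, Kupffer cell identity, complement, iron and heme handling, lipid handling, scavenging and efferocytosis, alternative activation, NF-kB targets, neutrophil granule proteins, aged or tumour-associated neutrophil, dendritic cell maturation, glycolysis and hypoxia, oxidative phosphorylation, dissociation and heat-shock stress, RNA of hepatocytes, melanoma, erythroid cells, neutrophils and immunoglobulin, and sex-linked genes. For each list the median of log2((CPM Vsig4 KO + 10)/(CPM WT + 10)) was taken over members with at least 20 UMIs in a class. As a description, not a test, its percentile was taken among 10000 random lists matched on CPM in 20 bins. Not every list is given in every class: the pairs of list and class printed were picked after the values had been seen, and each list is given at least once.

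Genes were named by a rule of size fixed beforehand: among genes with at least 50 UMIs and a UMI in at least 10% of cells in 1 library, the 12 highest and 12 lowest in CD8 T cell-like cells, the 6 highest and 6 lowest in the other classes, up to 4 members of each list, and Cd5 with a set of T cell and macrophage genes by name. The text gives the genes of this rule that belong to the lists or stand out, a choice made after their values were seen. Shares of cells with a UMI were computed after each cell had been thinned to 1000 UMIs. The alternatives were other cell filters, no doublet removal, other clustering resolutions, each library clustered on its own and other denominators. Further ones were thinning of the deeper library to the shallower median UMIs per cell in each class, other scalings, other pseudocounts and a higher count minimum.

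The steps from class sums onward (ratios, intervals, list percentiles and thinning) were tested on simulated data. Clustering, naming of clusters and doublet removal were not tested in this way. In a simulated class with 6332 genes, 200 of them changed 2-fold, 87.5% of the changed genes came out at least 1.5-fold apart in the right direction, and so did 0.033% of the others in either direction. The ratio intervals held the true ratio for 95.7% of genes. No differences between mice, sorts or libraries were simulated. These values therefore cover counting error only and do not show how often such differences would pass 1.5-fold. A list of 15 changed genes was at the 100th percentile of random lists and a list of 15 unchanged genes at the 3.25th. A low or high percentile can thus arise without a change. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.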

Results

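The data are single-cell RNA profiles of live CD45+ cells sorted from livers with B16F10 melanoma metastases, 1 library from WT and 1 from Vsig4 KO mice. VSIG4 is a complement receptor of the immunoglobulin superfamily carried by Kupffer cells, the resident macrophages of the liver, and the series title places the question in how Kupffer cells set T cell responses through binding of VSIG4 to the T cell receptor regulator CD5. The WT library gave 6491 cells with a median of 3033 UMIs and 1363 genes, and the Vsig4 KO library 5479 cells with a median of 3264 UMIs and 1437 genes. No replicate of either genotype was sequenced, so all differences below are between 2 libraries and carry intervals of counting error only. Ratios are Vsig4 KO over WT, and list medians are on the log2 scale.

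Vsig4 was nearly absent from the knockout library. The gene (ENSMUSG00000044206, mm10 chromosome X, 96247203 to 96293438, minus strand) gave 43 UMIs in 19 WT cells, or 1.64 CPM (95% interval 1.18 to 2.20). It gave 3 UMIs in 3 Vsig4 KO cells, or 0.128 CPM (0.0264 to 0.375), a ratio of 0.0783 (0.0155 to 0.245). Of the WT UMIs, 35 came from 15 cells of cluster 17, which was led by macrophage genes, while the 143 Vsig4 KO cells of that cluster gave 0. Clustering the macrophage-like cells once more gave a Kupffer cell-like sub-cluster of 20 WT and 10 Vsig4 KO cells led by Cd5l, Clec4f and Marco. There Vsig4 had 29 UMIs in 12 WT cells and 0 in the Vsig4 KO cells, 6.41-fold lower against a floor of 3 counts over the group (interval of the ratio 0 to 0.205). Clec4f, a Kupffer cell lectin, was at 2007 CPM in the WT and 2909.9 CPM in the Vsig4 KO cells of this sub-cluster (ratio 1.45, 1.04 to 2.02). Timd4, a receptor of embryo-derived Kupffer cells, was at 360.2 and 388 CPM (1.08, 0.428 to 2.61). Kupffer cell-like cells made up 0.308% of WT and 0.183% of Vsig4 KO cells, too few for a profile of their own. A gene-level count cannot show which part of the Vsig4 transcript was left.

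Lymphocytes held a larger share and monocytes and macrophages a smaller share of the Vsig4 KO library. B cell-like cells were 27.9% (26.9 to 29.1) of WT and 36.2% (34.9 to 37.5) of Vsig4 KO cells, a ratio of 1.30 (1.22 to 1.38). T cell-like classes together were 23.1% (22.1 to 24.1) and 29.0% (27.8 to 30.2), a ratio of 1.26 (1.17 to 1.35). Within them CD8 T cell-like cells were 9.97% (9.25 to 10.7) and 11.5% (10.7 to 12.4), conventional CD4 T cell-like cells 7.67% (7.04 to 8.35) and 9.31% (8.55 to 10.1), a ratio of 1.21 that was 2.29 with each library clustered on its own, and regulatory T cell-like cells 1.20% (0.951 to 1.498) and 1.53% (1.22 to 1.89). Monocyte-like and macrophage-like cells together were 16.4% (15.5 to 17.3) and 8.47% (7.74 to 9.24), a ratio of 0.517 (0.463 to 0.577). NK cell-like cells were at 9.81% (9.10 to 10.6) and 7.88% (7.18 to 8.63), and neutrophil-like cells at 1.39% (1.12 to 1.70) and 0.967% (0.725 to 1.26). The conventional dendritic cell classes were lower as well, cDC1-like cells at 2.17% (1.83 to 2.56) and 1.55% (1.24 to 1.91) and cDC2-like cells at 4.87% (4.36 to 5.42) and 3.03% (2.59 to 3.52). Clusters without a name held 6.01% of WT and 4.05% of Vsig4 KO cells. The CD45+ sort and the digestion can set these shares.

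**Figure D1:**
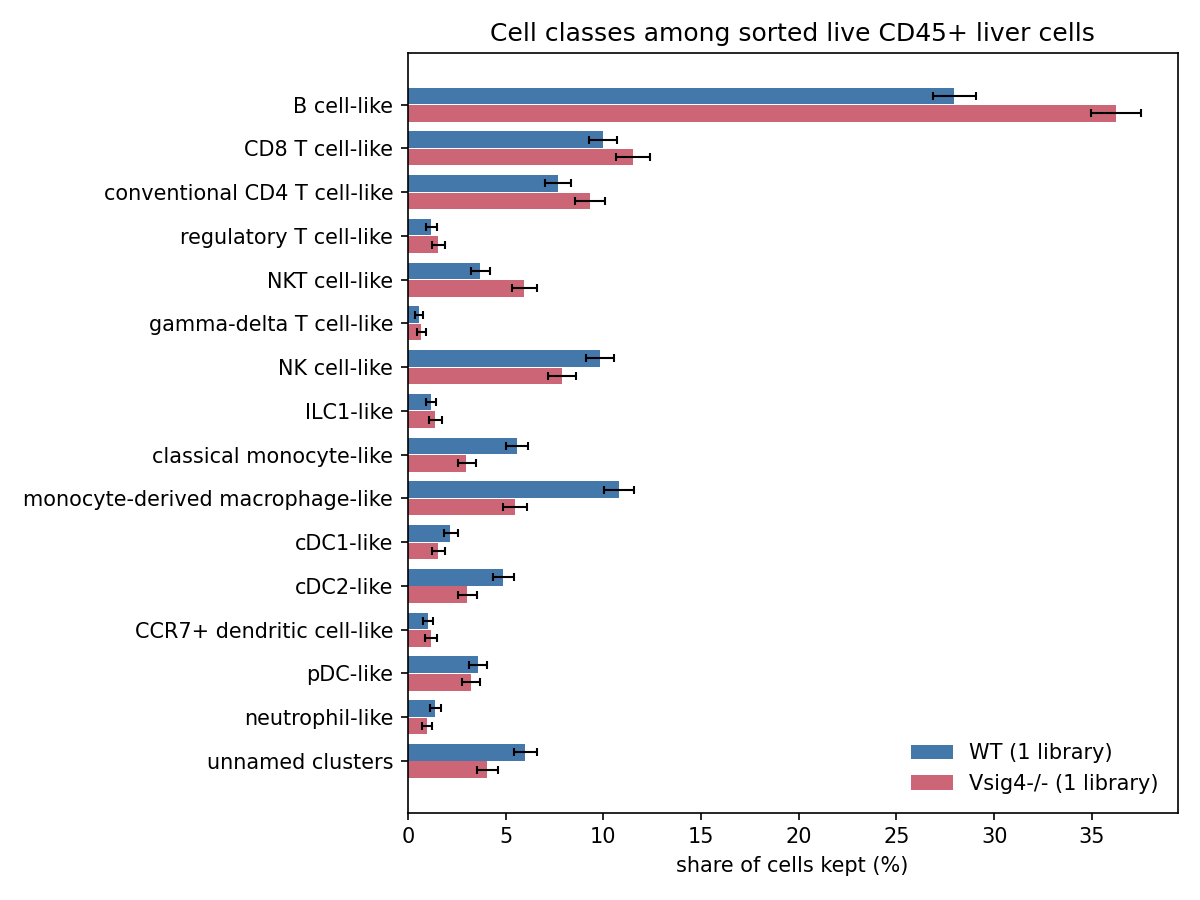
Share of the cells kept (%) in the immune cell classes named on the axis and in the unnamed clusters of the WT and Vsig4 KO (Vsig4-/-) libraries, with exact 95% binomial intervals as error bars; gamma-delta T cell-like cells had under 50 cells per library. B cell-like cells stand at 27.9% and 36.2%, and monocyte-derived macrophage-like cells at 10.8% and 5.48%.

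The split between monocyte-like and macrophage-like cells depended on the clustering. Classical monocyte-like cells, 1 cluster, were at 5.58% (5.03 to 6.16) and 2.99% (2.56 to 3.48), a ratio of 0.537 (0.444 to 0.647). Monocyte-derived macrophage-like cells were at 10.8% (10.1 to 11.6) and 5.48% (4.89 to 6.11), a ratio of 0.507 (0.441 to 0.581). Among these, cluster 12 held 480 WT and 157 Vsig4 KO cells (share ratio 0.388, 0.322 to 0.465), and cluster 17 held 186 and 143 (0.911, 0.727 to 1.14). Cluster 22, with a median of 705 UMIs, held 35 WT cells and 0 Vsig4 KO cells. The class was mixed. When it was clustered once more, 166 WT and 41 Vsig4 KO cells scored highest as classical and next as non-classical monocytes, and got no name. Another 37 and 17 were named classical monocytes. At resolution 2.5, 398 cells formed a non-classical monocyte-like cluster. The macrophage ratio was 0.967 with at most 5% mitochondrial UMIs and 0.949 at resolution 0.8. With each library clustered on its own it was 1.06, that of classical monocyte-like cells 0.916, that of the 2 classes together 0.964, that of CD8 T cell-like cells 0.973 and that of conventional CD4 T cell-like cells 2.29. There 573 WT cells, tied between the 2 classes, 312 WT cells nearest to conventional CD4 T cells and 181 Vsig4 KO cells nearest to CD8 T cells got no name. With unnamed clusters given their nearest class, the ratio was 0.365 for classical monocyte-like cells, 0.483 for the 2 classes together, 1.30 for CD8 T cell-like cells and 1.06 for conventional CD4 T cell-like cells.

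CD8 T cell-like cells of the Vsig4 KO library carried more RNA of granzymes and other cytotoxic effectors. Gzma, a granule protease, was at 224 CPM (206 to 243) in WT and 509 CPM (484 to 536) in Vsig4 KO, a ratio of 2.27 (2.06 to 2.51). Gzmk had a ratio of 2.28 (1.92 to 2.72), and Gzmb was at 113 CPM (101 to 127) and 238 CPM (220.4 to 256), a ratio of 2.10 (1.83 to 2.41). Zeb2, a transcription factor of terminal effector cells, had a ratio of 1.89 (1.46 to 2.45). The cytotoxic effector list had a median of 0.38 (0.19 to 0.52), the 100th percentile of random lists, with 7 of 19 measured members at least 1.5-fold higher and 0 lower. Some effectors of the list did not share this: Prf1, the pore-forming perforin, had a ratio of 1.03 (0.796 to 1.33), Tnf 0.942 (0.674 to 1.32), and Ifng was lower at 108 and 74.0 CPM (0.682, 0.569 to 0.817). Xcl1, a chemokine gene, had a ratio of 1.88 (1.60 to 2.21), but below 1 under 3 alternatives. The list's difference lay in 1 of the 2 CD8 T cell-like clusters: the list's median was 0.60 in cluster 15 and -0.04 in cluster 19, the larger one. With at least 500 genes per cell, at resolution 0.8 or from 200 other random starts it was between 0.17 and 0.19.

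Cells with a Gzmb UMI were more frequent among Vsig4 KO CD8 T cell-like cells. After thinning to 1000 UMIs they made up 6.70% (4.89 to 8.92) of 642 WT cells and 13.2% (10.7 to 16.2) of 612 Vsig4 KO cells, with 5 and 18 shallower cells left out. Before thinning, at medians of 3730 and 4199 UMIs, the shares were 14.4% and 20.8%. In B cell-like cells, which should lack Gzmb, 0.284% and 0.157% had a UMI after thinning, at medians of 2361 and 2733 UMIs.

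**Figure D2:**
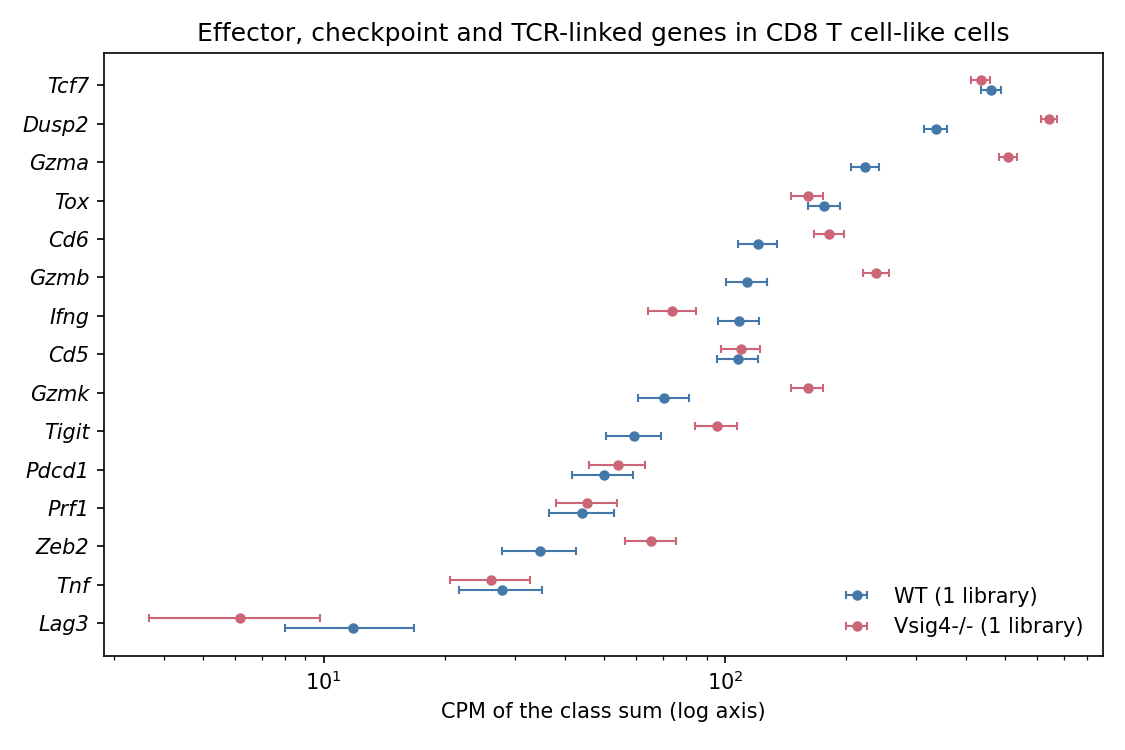
CPM (log axis) of 15 effector, checkpoint and TCR-linked genes in CD8 T cell-like cells of the WT and Vsig4 KO libraries, as sums over the class with exact 95% Poisson intervals. Gzma stands at 224 and 509 CPM, while Cd5 stands at 108 and 109.8 CPM.

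Checkpoint genes of CD8 T cell-like cells went in both directions. The checkpoint and exhaustion list had a median of 0.10 (-0.03 to 0.24), the 83.4th percentile, but 0.24 with at most 5% mitochondrial UMIs and 0.29 in cluster 15. Tigit, an inhibitory receptor, was higher (ratio 1.61, 1.32 to 1.97), as was Cd160 (1.68, 1.26 to 2.27). Lag3 was lower on few UMIs, 31 and 18 (0.525, 0.277 to 0.969), while Pdcd1, which encodes PD-1, had a ratio of 1.08 (0.854 to 1.38), Havcr2 1.38 (0.723 to 2.72) and Tox 0.910 (0.799 to 1.04). The naive and memory list was at 0.00 (-0.07 to 0.05), but at -0.19 in cluster 15, and Tcf7, a factor of naive and stem-like cells, had a ratio of 0.940 (0.868 to 1.02). Mki67 was at 20 and 22 UMIs (0.995, 0.518 to 1.92). A separate cluster of cycling cells, 50 WT and 46 Vsig4 KO cells, was kept out of every class. It scored next highest for CD8 T cell markers, so the Mki67 value leaves out cycling cells of that cluster.

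Cd5 itself did not differ in CD8 T cell-like cells at this depth. The gene (ENSMUSG00000024669, chromosome 19, 10717116 to 10739002, minus strand) was at 108 CPM (95.5 to 121) and 109.8 CPM (98.1 to 123), a ratio of 1.02 (0.866 to 1.20). After thinning, 9.50% (7.35 to 12.04) of WT and 9.31% (7.13 to 11.9) of Vsig4 KO cells had a Cd5 UMI, and 28.7% and 29.5% before. In pDC-like cells the thinned shares were 0.866% and 0%, of which the latter allows up to 2.29%, at medians of 5719 and 6280 UMIs with 1 and 17 cells left out. Cd6, a receptor related to CD5, was higher (1.505, 1.31 to 1.73), as was Cd3e, a chain of the TCR complex (1.27, 1.19 to 1.36). The CD5 and TCR signalling list had a median of 0.11 (0.02 to 0.14), the 95.1th percentile, with 0 of 23 members at least 1.5-fold apart.

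Glycolysis genes of CD8 T cell-like cells were higher as a group in the Vsig4 KO library. The glycolysis and hypoxia list had a median of 0.26 (0.11 to 0.31), the 100th percentile, with 17 of 19 members higher, among them the glycolytic enzyme genes Eno1 (1.501, 1.36 to 1.66) and Aldoa (1.42, 1.29 to 1.57). The oxidative phosphorylation list was at -0.06 (-0.09 to 0.02). The T cell activation list had a median of 0.18 (0.03 to 0.22), led by Dusp2, a phosphatase gene induced on activation (1.92, 1.77 to 2.08). The tissue residency list was at 0.10 (0.02 to 0.25), though -0.06 in cluster 19, led by the chemokine receptor gene Ccr2 (2.13, 1.64 to 2.79). The dissociation and heat-shock stress list was at 0.04 (-0.10 to 0.10), though Hspa1a, an inducible heat-shock gene, was lower (0.488, 0.454 to 0.525). Among the genes farthest apart were Cdk5rap1 (6 and 121 UMIs; ratio 18.2, 8.14 to 50.7), Slc15a2 (2.71, 2.19 to 3.38) and Camk2b (2.05, 1.70 to 2.48), all higher, and Ctse, S100a4 and S100a6, lower with ratios of 0.392 (0.324 to 0.473), 0.523 (0.456 to 0.599) and 0.568 (0.527 to 0.611). Cdk5rap1, Slc15a2, Camk2b and Ctse differed in the same direction in most other classes too.

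Conventional CD4 T cell-like cells of the Vsig4 KO library had more RNA of early response and other activation genes. The T cell activation list had a median of 0.41 (0.36 to 0.61), the 100th percentile, with 15 of 17 members higher, 7 of them at least 1.5-fold. Egr2 (3.37, 1.77 to 6.95), Egr1 (2.01, 1.64 to 2.49) and Nr4a1 (1.71, 1.52 to 1.93), early response genes, and Nfkbid (1.72, 1.41 to 2.12) were among them. Such genes were higher in ILC1-like cells too, which lack a TCR, with Nr4a1 at 3.54 (2.48 to 5.15) and Nfkbid at 3.91 (2.29 to 7.0). The rise in conventional CD4 T cell-like cells therefore does not single out TCR signals. The list's median was 0.52 in both clusters of the class, but 1.42 with each library clustered on its own, where 312 WT cells nearest to this class got no name. The stress list, which shares Egr1, was at 0.01 (-0.07 to 0.19) with members in both directions, such as Btg2 (1.798, 1.63 to 1.99) higher and Hspa1a (0.675, 0.629 to 0.724) lower. The CD5 and TCR signalling list was at 0.13 (0.03 to 0.22), with Cd6 (1.67, 1.45 to 1.93) and the adaptor gene Lat (1.40, 1.27 to 1.54) higher. Cd5 was at 276.0 and 241 CPM (0.874, 0.765 to 1.0003) in the whole class. In cluster 20, which is part of it, Cd5 was lower at 122 and 93 UMIs (0.578, 0.437 to 0.763). Cluster 0, the other part, had Cd5 among its top 10 genes. The lower Cd5 of cluster 20 therefore does not stand for the class, and whether a mix of cells sets it was not tested. The glycolysis and hypoxia list had a median of 0.26 (0.18 to 0.38), with Aldoa at 1.78 (1.58 to 2.01) and Ldha, which encodes lactate dehydrogenase A, at 1.41 (1.28 to 1.57). The naive and memory list was at 0.08 (-0.03 to 0.13) and the checkpoint and exhaustion list at -0.07 (-0.20 to 0.09). Ctla4 had a ratio of 1.82 (1.59 to 2.10), but 0.883 from other random starts and 0.924 at resolution 0.8, where 634 and 617 cells tied between conventional CD4 and regulatory T cells got no name. Lgals3, which encodes galectin 3, was lower (0.447, 0.354 to 0.563), but at 4.38 with each library clustered on its own, and Ctse was lower (0.361, 0.294 to 0.442).

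Regulatory T cell-like cells, 78 WT and 84 Vsig4 KO cells, had members of the regulatory T cell list in both directions. Its median was 0.00 (-0.06 to 0.24), with 7 of 13 members higher and 6 lower, and Foxp3, the lineage factor, a ratio of 0.966 (0.757 to 1.23). Pdcd1 was higher at 306 and 399 CPM (1.31, 1.05 to 1.63), as was Bhlhe40 (1.59, 1.32 to 1.93), and Eomes was lower on 24 and 7 UMIs (0.225, 0.0818 to 0.538). The checkpoint and exhaustion list had a median of 0.14 (0.05 to 0.32). Cd5 was lower here, at 343 CPM (289.9 to 404) and 189 CPM (154 to 229), a ratio of 0.549 (0.423 to 0.711), while the CD5 and TCR signalling list was at -0.02 (-0.13 to 0.08). After thinning, with 1 and 0 cells left out, 28.6% (18.8 to 40.0) of WT and 16.7% (9.42 to 26.4) of Vsig4 KO cells had a Cd5 UMI, against 69.2% and 59.5% before at medians of 4356 and 5138 UMIs. Prf1 (0.575, 0.367 to 0.892), the chemokine gene Ccl4 (0.474, 0.408 to 0.550), Cd3d (0.793, 0.692 to 0.910) and Hspa1a (0.197, 0.152 to 0.254) were lower, and Tgfb1, a suppressive cytokine gene of the regulatory T cell list, was higher (1.46, 1.14 to 1.88). With each library clustered on its own the Cd5 ratio was 1.66, and Prf1, Ccl4, Cd3d and Hspa1a were above 1 too, so their direction rests on which cells were called regulatory.

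NK cell-like cells had more RNA of cytotoxic genes and, outside the separate cluster of cycling cells, less of cell cycle genes. The class joined cluster 14, with Gzma and Prf1 among its top 10 genes, and cluster 3, with Eomes and Ctla2a among its own. Cluster 14 held 453 WT and 328 Vsig4 KO cells and cluster 3 held 184 and 104, so cluster 14 made up more of the Vsig4 KO class. How far this mix sets the values of the NK class was not tested. The cytotoxic effector list had a median of 0.23 (0.17 to 0.32), the 99.9th percentile, with 16 of 20 members higher. Prf1 was at 485 and 731 CPM (1.51, 1.38 to 1.64) and Gzmb at 451 and 671 CPM (1.49, 1.36 to 1.63). Klrg1, a receptor of mature NK cells, had a ratio of 1.84 (1.51 to 2.26), and Tbx21, which encodes T-bet, 1.48 (1.30 to 1.68). Ifng was higher as well (1.36, 1.19 to 1.56), unlike in the CD8 T cell-like class, though that contrast was not tested. The proliferation list had a median of -0.45 (-0.58 to -0.17) over 7 measured members, with Mki67 at 37 and 13 UMIs (0.464, 0.226 to 0.893) and Pcna at 0.670 (0.523 to 0.855). The separate cluster of cycling cells was not counted here, and how many of its cells were NK cells was not tested. The lower list therefore does not show less cycling among all NK cells. Tcf7 was lower (0.665, 0.563 to 0.784). The checkpoint and exhaustion list had a median of 0.19 (0.08 to 0.32), led by Entpd1 (1.93, 1.41 to 2.67), and Dusp2 was higher (2.33, 2.18 to 2.49), beside a stress list at 0.09 (0.03 to 0.16). Thinned shares of cells with a Prf1 UMI were 35.8% (32.0 to 39.7) and 47.5% (42.6 to 52.4) with 17 and 11 cells left out, against 63.6% and 78.2% before thinning at medians of 2877 and 3258 UMIs. In B cell-like cells they were 0.170% and 0.0525%.

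**Figure D3:**
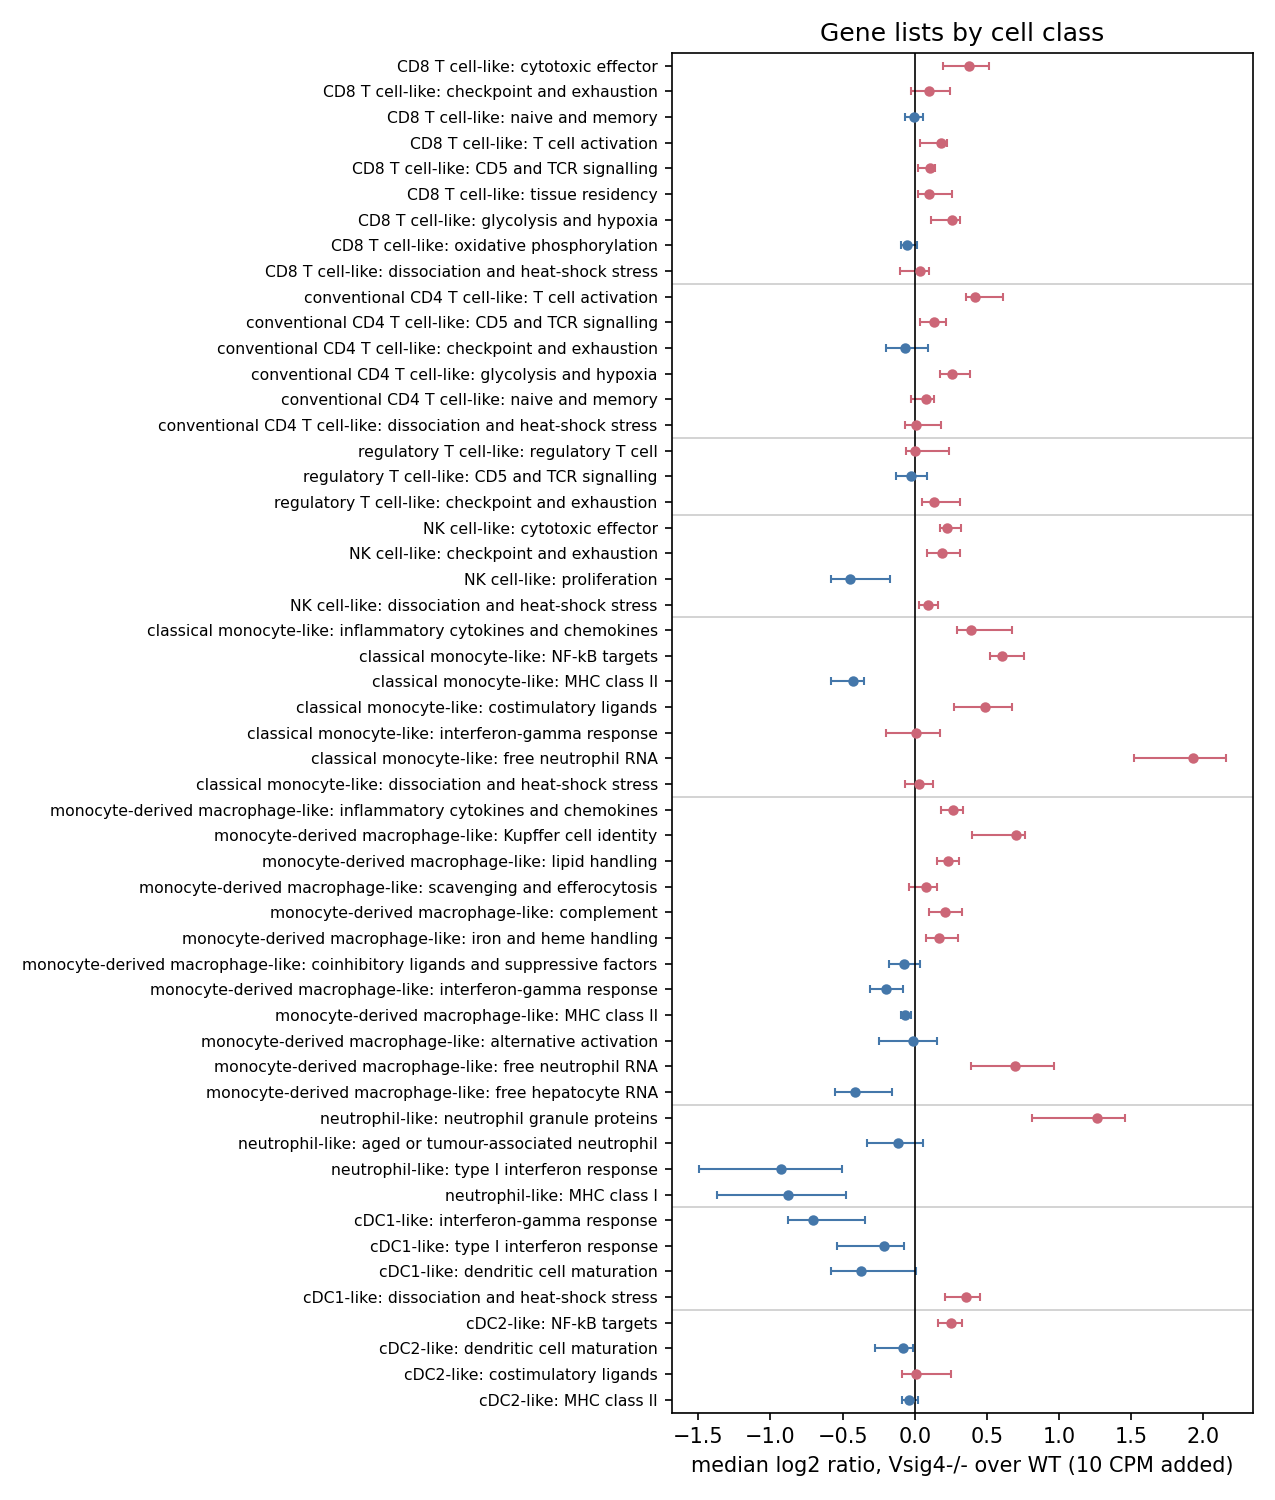
Median log2 ratio (Vsig4 KO, shown as Vsig4-/-, over WT, with 10 CPM added) of selected lists in 9 classes, with 95% intervals from Poisson draws. The pairs of list and class were picked after the values had been seen. Red marks medians above 0 and blue below. The cytotoxic effector list stands at 0.38 in CD8 T cell-like cells and the NF-kB list at 0.60 in classical monocyte-like cells.

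Classical monocyte-like cells of the Vsig4 KO library had an inflammatory profile with less MHC class II. The NF-kB target list had a median of 0.60 (0.52 to 0.76), the 100th percentile, with all 14 members higher, among them the feedback inhibitors Nfkbia (1.82, 1.74 to 1.90) and Tnfaip3 (1.80, 1.65 to 1.97). That median was 0.30 with at most 5% mitochondrial UMIs and at resolution 0.8. The inflammatory cytokine and chemokine list had a median of 0.39 (0.29 to 0.67), with 8 of 18 members at least 1.5-fold higher. Il1b was at 2348 and 6379 CPM (2.72, 2.62 to 2.81), Cxcl10 at 281 and 965 CPM (3.43, 3.12 to 3.79), Cxcl1 at 70.3 and 279 CPM (3.97, 3.28 to 4.83), and Ptgs2, the inducible cyclooxygenase, had a ratio of 2.81 (2.55 to 3.09). The acute-phase genes Saa3 (60 and 469 UMIs; 13.7, 10.4 to 18.2) and Lrg1 (4 and 51 UMIs; 22.3, 8.19 to 84.9) were far higher. The costimulatory ligand list had a median of 0.49 (0.27 to 0.67), with Tnfsf9 at 1.90 (1.65 to 2.17) and Cd86 at 1.49 (1.32 to 1.69). The MHC class II list was at -0.43 (-0.58 to -0.35), with H2-Aa at 0.594 (0.524 to 0.672), H2-Eb1 at 0.578 (0.484 to 0.688) and Ciita, the class II transactivator, at 0.392 (0.197 to 0.723). Interferon-gamma response genes were at 0.01 (-0.20 to 0.17), and Chil1 was at 637 and 19 UMIs (0.0521, 0.0312 to 0.0821).

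Neutrophil markers were also higher in these monocyte-like cells. The neutrophil RNA list had a median of 1.93 (1.52 to 2.16) over 3 measured members, with S100a8 at 32.2 and 164 CPM (5.10, 3.88 to 6.76) and Lcn2 at 7.61 and 57.1 CPM (7.505, 4.38 to 13.6). The stress list was at 0.03 (-0.06 to 0.13). The inflammatory median was between 0.25 and 2.61 over the alternatives, and with each library clustered on its own H2-Aa was at 4.19 and the MHC class II list at 0.72, so the lower MHC class II depended on the clustering.

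Monocyte-derived macrophage-like cells gave list differences that depended on the cluster. The inflammatory list had a median of 0.26 (0.18 to 0.34), the 100th percentile, with Cxcl1 at 145 and 437 CPM (3.01, 2.70 to 3.36) and Cxcl9, a chemokine for CXCR3+ T cells, at 117 and 177 CPM (1.51, 1.31 to 1.74). It was 0.29 in cluster 12 but -0.02 in cluster 17, and -0.04 at resolution 0.8. The Kupffer cell identity list had a median of 0.70 (0.39 to 0.76) with 9 of 17 members at least 1.5-fold higher, among them the scavenger receptor gene Marco (5.18, 3.10 to 8.94), the iron exporter gene Slc40a1 (3.41, 2.31 to 5.08), Cd163 (6 and 18 UMIs; 6.34, 2.41 to 19.5) and Clec4f (2.03, 1.46 to 2.82, but 0.884 with at most 5% mitochondrial UMIs). Few cells held these UMIs: 1.43% of WT and 4.33% of Vsig4 KO cells had Marco, 3.85% and 7.33% Slc40a1, and 0.713% and 2.33% Cd163, and in Vsig4 KO 75 UMIs of Clec4f and 38 of the 54 of Marco lay in 7 cells each of the Kupffer cell-like sub-cluster. Timd4 had a ratio of 1.37 (0.579 to 3.09). The median of the Kupffer cell identity list was 0.11 in cluster 12 and 0.33 in cluster 17 taken alone. Cluster 17, which holds the Kupffer cell-like cells, made up more of the Vsig4 KO class, but whether that mix sets the class median was not tested.

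The other lists of macrophage functions had medians between -0.20 and 0.23. The lipid handling list was at 0.23 (0.16 to 0.31), with Trem2, a lipid-sensing receptor gene, at 1.49 (1.27 to 1.74), but at 0.0038 in cluster 12 and 0.13 in cluster 17. The complement list was at 0.21 (0.10 to 0.33), iron and heme handling at 0.17 (0.08 to 0.30), scavenging and efferocytosis at 0.08 (-0.04 to 0.16), alternative activation at -0.01 (-0.25 to 0.16), coinhibitory ligands and suppressive factors at -0.08 (-0.18 to 0.04), and MHC class II at -0.07 (-0.10 to -0.02). Of these, complement was at -0.0338 and iron and heme handling at -0.0360 with each library clustered on its own, and MHC class II at 0.0714 at resolution 2.5. The interferon-gamma response list was at -0.20 (-0.31 to -0.08) but turned positive under 6 alternatives, and Cd274, which encodes PD-L1, was at 135 and 103 CPM (0.760, 0.640 to 0.899) but above 1 under 3 of them. Tnf (1.80, 1.65 to 1.98) and C1qa (1.49, 1.41 to 1.58) were higher and Ciita (0.562, 0.432 to 0.724) and Slpi (0.255, 0.212 to 0.304) lower, each with the other direction under at least 1 alternative clustering. Chil1 had 576 UMIs in WT and 0 in Vsig4 KO cells, 90.9-fold lower against a floor of 3 counts (interval of the ratio 0 to 0.0136). The chemokine gene Ccl24 had a ratio of 0.239 (0.168 to 0.332). Ppfia4 went the other way with 2 and 48 UMIs (50.7, 13.3 to 431). Beside these, RNA of neutrophils (median 0.70, 0.39 to 0.96, over 2 members) was higher and RNA of hepatocytes (-0.42, -0.55 to -0.16, over 8 members) lower in the Vsig4 KO class, though the latter was positive under 5 alternatives.

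Neutrophil-like cells, 90 WT and 53 Vsig4 KO cells, had more granule protein RNA and less interferon-linked RNA in the Vsig4 KO sum, part of it from few cells. The granule protein list had a median of 1.26 (0.81 to 1.45), the 100th percentile, with all 9 measured members higher. Camp (3.73, 3.33 to 4.20), Ngp (3.01, 2.68 to 3.39) and Lcn2 (2.5035, 2.18 to 2.88), which are made by young neutrophils, were among them. Camp UMIs lay in 2.22% of WT and 13.2% of Vsig4 KO cells and Ngp UMIs in 6.67% and 13.2%, so the ratios of Camp and Ngp rest on few cells. MHC class I genes had a median of -0.88 (-1.37 to -0.47), with the immunoproteasome gene Psmb8 at 33 and 8 UMIs (0.324, 0.129 to 0.715). The aged or tumour-associated neutrophil list was at -0.12 (-0.33 to 0.06), with Cxcl3 (0.377, 0.305 to 0.462) and Ccl3 (0.412, 0.362 to 0.468) lower. RNA typical of other cell types was lower too, with Apoe, a macrophage gene, at 44 and 6 UMIs (0.182, 0.0634 to 0.429) and Gzma at 22 and 0 UMIs. Neutrophil-like cells had low depth, with medians of 1286 and 2154 UMIs.

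Conventional dendritic cell classes of the Vsig4 KO library had less RNA of some chemokines. In cDC1-like cells the interferon-gamma response list had a median of -0.70 (-0.88 to -0.35) with 13 of 14 members lower, among them Cxcl9 (394 and 20 UMIs; 0.0735, 0.0444 to 0.115), Irf1 (0.463, 0.298 to 0.699) and Cd274 (29 and 6 UMIs; 0.299, 0.102 to 0.734). The type I interferon list was at -0.22 (-0.54 to -0.07), with Isg15 at 0.383 (0.231 to 0.612). The dendritic cell maturation list was at -0.37 (-0.58 to 0.01), with Cd40 (0.482, 0.236 to 0.923) and Ccl17 (24 and 3 UMIs; 0.181, 0.0349 to 0.596) lower and Ccl22 (3.41, 1.78 to 6.90) higher. The stress list was higher beside these at 0.35 (0.21 to 0.45), with Egr1 at 3.35 (2.37 to 4.80), and the median gene of the class was shifted by 0.10. In cDC2-like cells Cxcl10 (0.316, 0.246 to 0.402), whose UMIs lay in 9.81% of WT and 12.7% of Vsig4 KO cells, and Ccl17, a chemokine for CCR4+ cells (205 and 13 UMIs; 0.103, 0.0541 to 0.181), were lower. Their NF-kB target list was at 0.25 (0.16 to 0.33), with Nfkbia at 1.67 (1.58 to 1.76), the maturation list at -0.08 (-0.28 to -0.01) but 0.16 without doublet removal, the costimulatory list at 0.01 (-0.09 to 0.25) with Tnfsf9 at 1.65 (1.49 to 1.83), and the MHC class II list at -0.04 (-0.09 to 0.02). Ppfia4 was higher in both, with 1 and 74 UMIs in cDC1-like (107, 18.6 to 4287) and 7 and 171 UMIs in cDC2-like cells (39.8, 18.9 to 101).

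B cell-like cells had slightly more MHC class II RNA and less heat-shock RNA. The MHC class II list had a median of 0.14 (0.10 to 0.17), with 10 of 11 members higher, among them Cd74, the invariant chain gene (1.24, 1.22 to 1.25), and H2-DMb2 (1.39, 1.32 to 1.47). The stress list was at -0.14 (-0.22 to -0.07), with Hspa1a (0.564, 0.544 to 0.585) and Hspa1b (0.548, 0.533 to 0.564) lower and the antiproliferative gene Btg2 (1.57, 1.48 to 1.66) higher. Camk2b (3.14, 2.94 to 3.36) and Slc15a2 (3.39, 2.97 to 3.87) were higher and Ctse, an aspartic protease gene, lower (0.296, 0.259 to 0.339). Cluster 4 held 390 WT and 741 Vsig4 KO B cell-like cells and cluster 6 held 615 and 274, so the class is compared whole although its clusters split by library. H2-DMb2 and H2-Ob, of the MHC class II list, were among the top 10 genes of cluster 4 but not of cluster 6. Whether this mix sets the MHC class II median was not tested.

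RNA of hepatocytes, melanoma cells, erythroid cells, neutrophils and immunoglobulin was compared over all cells kept. Hepatocyte RNA had a median of -0.16 (-0.18 to -0.08), with Alb at 6.47 and 3.68 CPM, and melanoma RNA 0.15 (0.10 to 0.20), with Pmel, a pigment cell gene, at 6.97 and 10.9 CPM. Melanoma cell-like cells, a cluster that scored next highest for liver endothelial markers, were 42 WT and 49 Vsig4 KO cells despite the CD45+ sort. Erythroid RNA was at -1.74 (-1.81 to -1.68), with Hbb-bs at 2059 and 28 UMIs, neutrophil RNA at 0.23 (0.14 to 0.34) with Camp at 15.2 and 47.5 CPM, and immunoglobulin RNA at 0.18 (0.15 to 0.20) with Jchain at 603 and 981 CPM. The dissociation and heat-shock stress list was at -0.08 (-0.12 to -0.05), with Hspa1a at 1273 and 752 CPM (0.590, 0.580 to 0.601). Sex-linked genes had a median of 0.04 (-0.03 to 0.09), with Ddx3y at 65.8 and 67.9 CPM and Eif2s3y at 49.4 and 29.8 CPM.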

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

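The comparison of cell classes in this part was chosen after the values were seen. Type I interferon response genes, which cells switch on when interferon alpha or beta is bound, differed in opposite directions in pDC-like and neutrophil-like cells, and this opposite direction is what singled them out. In pDC-like cells the list had a median of 0.64 (0.38 to 0.83), with 7 of 12 measured members at least 1.5-fold higher in Vsig4 KO, among them Isg15 (3.58, 2.43 to 5.37), Slfn5 (5.14, 2.68 to 10.6) and Usp18 (2.26, 1.40 to 3.71). The dissociation and heat-shock stress list of pDC-like cells was lower at the same time, at -0.66 (-0.75 to -0.42). In neutrophil-like cells the median was -0.93 (-1.50 to -0.50), with 5 of 8 members at least 1.5-fold lower, among them Oasl1 (38 and 6 UMIs; 0.211, 0.0729 to 0.503) and Rsad2 (24 and 6 UMIs; 0.334, 0.112 to 0.839). These UMIs lay in few cells: 6.67% of WT and 9.43% of Vsig4 KO cells held Oasl1, so its lower sum does not mean fewer cells with it, Isg20 was held by 11.1% and 9.43%, and Rsad2 by 13.3% and 3.77%. The macrophage gene Apoe was lower in neutrophil-like cells as well, at 44 and 6 UMIs. The difference between the classes was not tested, and no explanation of it was tested.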

How the results depend on the processing

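Other random starts of the clustering, clusters taken on their own, the Kupffer cell-like sub-cluster, macrophages without cluster 22, monocytes and macrophages as 1 class and unnamed clusters of the single libraries given their nearest class were chosen after the data were seen; the other alternatives were fixed before. Of the CPM ratios of named genes, 1323 values under the alternatives stayed within the interval as reported, 184 left it with the same direction and 28 changed direction. For list medians outside the main comparisons these counts were 769, 126 and 21, for those of the main comparisons 75, 22 and 3, for shares of main classes 59, 13 and 3, for other shares 59, 5 and 0, and for thinned shares of cells with a UMI 66, 2 and 0. The share ratio stayed between 1.27 and 1.32 for B cell-like, 0.781 and 0.808 for NK cell-like and 1.49 and 1.73 for NKT cell-like cells. Below, genes and shares are ratios and lists medians; mac stands for monocyte-derived macrophage-like and mono for classical monocyte-like cells. With each library clustered on its own, values were C1qa 0.932, Cd274 1.54, Ciita 4.68, Clec4f 0.901 and Slpi 25.3 in mac, H2-Aa 4.19 and H2-Eb1 4.69 in mono, Ccl4 15.4, Cd3d 1.54, Cd5 1.66, Hspa1a 1.53 and Prf1 4.05 in regulatory T cell-like cells, Lgals3 4.38 in CD4 and Xcl1 0.362 in CD8 T cell-like cells. Lists there were MHC class II 0.72 and inflammatory 2.61 in mono, complement -0.0338, inflammatory 0.46, interferon-gamma 0.33 and iron -0.0360 in mac, and activation 1.42 in CD4 T cell-like cells. Shares there were CD8 0.973, CD4 2.29, all T cells 1.43, mono 0.916, mac 1.06 and both together 0.964. In that clustering 573 WT cells tied between mono and mac, 312 WT cells tied between CD4 and regulatory T cells and 181 Vsig4 KO cells nearest to CD8 T cells got no name. With unnamed clusters given their nearest class, shares were CD8 1.30, CD4 1.06, mono 0.365, mac 1.06 and both together 0.483. With at most 5% mitochondrial UMIs, mac values were C1qa 0.994, Cd274 1.63, Clec4f 0.884, Tnf 0.350, complement -0.00319, inflammatory 0.55, interferon-gamma 0.44, hepatocyte RNA 0.60 and share 0.967; Xcl1 in CD8 was 0.972, the CD8 checkpoint list 0.24 and mono NF-kB 0.30. With at least 500 genes, values were Il12b 2.32 and maturation 0.0273 in cDC2, cytotoxic 0.17 in CD8 and 0.33 in NK, inflammatory 0.84 in mono and 0.0525 in mac, interferon-gamma 0.26 and hepatocyte RNA 0.50 in mac, and shares of 0.412 for mono and 0.671 for mac. At resolution 0.8, mac values were C1qa 0.9995, Cd274 1.27, Tnf 0.267, inflammatory -0.0441, interferon-gamma 0.25, iron -0.0195 and share 0.949, Ctla4 in CD4 was 0.924, CD8 cytotoxic 0.18, and mono NF-kB 0.30 and inflammatory 0.25. At resolution 2.5, mac values were Ciita 1.09, MHC class II 0.0714, hepatocyte RNA 0.39, inflammatory 0.0259, interferon-gamma 0.27 and share 0.677, Xcl1 in CD8 was 0.715 and the share of mono and mac together 0.663. Cells tied between CD4 and regulatory T cells, 617 at resolution 0.8 and 634 from other random starts, got no name. Other random starts gave Ctla4 0.883 in CD4, cytotoxic 0.19 in CD8, hepatocyte RNA 0.54 in mac and inflammatory 0.82 in mono. Without doublet removal, cDC2 Il12b was 2.38 and maturation 0.16, and mac hepatocyte RNA 0.52. Single clusters gave mac MHC class II 0.0473 in cluster 12, inflammatory -0.0166 and interferon-gamma 0.29 in cluster 17, CD8 checkpoint 0.29 and cytotoxic 0.60 in cluster 15, and cytotoxic -0.0438 and residency -0.0574 in cluster 19. With members of at least 100 UMIs the mono inflammatory list was at 1.01, and with 50 CPM added it was at 0.26, mono NF-kB at 0.51 and CD4 activation at 0.33, which the larger added value draws toward 0. The Vsig4 ratio in the Kupffer cell-like sub-cluster was 0. For the other settings the cause was not tested.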

Other observations

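The tests of the 3 patterns weighed here were chosen after the results were seen, apart from the median shift of NK markers in CD8 T cell-like cells. NKT cell-like cells, innate-like T cells abundant in mouse liver, were more frequent in the Vsig4 KO library, at 3.70% (3.25 to 4.19) and 5.97% (5.36 to 6.63), a ratio of 1.61 (1.36 to 1.91). They had more RNA of the early response genes Egr1 (4.73, 3.84 to 5.88) and Nr4a1 (2.73, 2.45 to 3.04), beside a T cell activation list at 0.13 (0.05 to 0.43) and a stress list at 0.34 (0.26 to 0.43). Their interferon-gamma response list was at -0.37 (-0.51 to -0.20), with Irf1 at 0.551 (0.424 to 0.715), while Ifng was at 1.13 (1.01 to 1.27). ILC1-like cells, liver-resident relatives of NK cells, had more activation RNA, with a list median of 1.11 (0.75 to 1.32) and Nfkbid (3.91, 2.29 to 7.0), Nr4a1 (3.54, 2.48 to 5.15) and Egr1 (3.39, 1.68 to 7.41) higher. Their cytotoxic effector list was at 0.27 (0.15 to 0.45), with Gzma at 1.77 (1.63 to 1.91), and the stress list, which shares some activation genes, at 0.34 (0.19 to 0.46).

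pDC-like cells, the main producers of type I interferon, had less heat-shock and early response RNA in the Vsig4 KO library, with a stress list at -0.66 (-0.75 to -0.42), Hspa1a at 0.345 (0.307 to 0.386) and Jun at 0.377 (0.337 to 0.422). Their MHC class I list was at 0.16 (0.08 to 0.29), with H2-Q7 at 1.49 (1.30 to 1.69), and their MHC class II list at 0.24 (0.09 to 0.27). CCR7+ dendritic cell-like cells, which carry antigen to lymph nodes, had more Il12b, a subunit gene of interleukin 12 and 23, at 375 and 1132 CPM (3.02, 2.44 to 3.74), and more Tnfsf9 (3.35, 2.06 to 5.66). Their MHC class II list was at -0.46 (-0.72 to -0.36), with H2-Aa at 0.586 (0.540 to 0.636), costimulatory ligands at -0.51 (-0.75 to -0.11), with Cd80 at 0.695 (0.540 to 0.892), and maturation genes at -0.17 (-0.33 to -0.05). In cDC2-like cells Il12b was at 84 and 3 UMIs instead (0.0582, 0.0118 to 0.176), but the ratio was 2.32 with at least 500 genes and 2.38 without doublet removal. pDC-like cells were at 3.57% and 3.21% of the libraries, CCR7+ dendritic cell-like cells at 1.02% and 1.17%, and ILC1-like cells at 1.17% and 1.39%.

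Higher granzyme RNA in CD8 T cell-like cells is the pattern nearest to the series' question. The cytotoxic effector list was higher in NK cell-like and ILC1-like cells too, which lack a TCR. The rise in CD8 T cell-like cells therefore does not single out TCR signals. NK cells or NK RNA among the CD8 T cell-like cells were argued against: NK markers outside the list had a median shift of 0.0791 (-0.117 to 0.195), whose upper bound passed the list's lower bound of 0.193, so a further test followed. Their summed CPM differed by 6.9716 (-20.2 to 34.2), against the 357 CPM that the NK share needed for the list would bring. Another mix of effector and naive cells stays open: with the WT cluster proportions in both libraries the median was 0.4068, but cluster 15 held 34.6% and 33.5% of the class, so the weights could not have moved it, and within cluster 15 the naive and memory list was at -0.19. A difference between mice or libraries stays open with 1 library per genotype, and so does an effect of Vsig4 loss, which the design cannot tell apart from it.

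The lower share of monocyte-like and macrophage-like cells in Vsig4 KO was weighed next. Dilution by more B cells alone was argued against, since among cells other than B cell-like cells the ratio was still 0.5841 (0.523 to 0.652). T cell-like classes, also at a higher share in Vsig4 KO (23.1% and 29.0%), stayed in that denominator. Dilution by B and T cells together was not tested and stays open. Loss of cells at the filters used here was argued against too: without doublet removal the ratio stayed within its interval of 0.463 to 0.577. Only 56 WT and 50 Vsig4 KO barcodes held over 10% mitochondrial UMIs. The percentages of barcodes kept differed by 0.803 points, a total that does not show which cell types were lost. The deposited barcodes started at 500 UMIs, so losses before that cannot be seen and stay open. Less tumour tissue in the sampled livers stays open, as does an effect of Vsig4 loss: melanoma cell-like cells had a ratio of 1.3822 (0.897 to 2.14), in a sort that removes them. Their cluster scored 3.415 for melanoma and 3.046 for liver endothelial markers, so it is not a clean measure of tumour. With each library clustered on its own the ratio was 0.964 without 573 WT cells left unnamed by a tie between the 2 classes, and 0.483 with unnamed clusters given their nearest class.

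In at least 6 cell classes, 8647 genes had enough UMIs. Without receptor and immunoglobulin segment genes, taken out after they had been seen, 20 were at least 1.5-fold apart in the same direction in at least 75% of these classes. The rule itself left out any gene that was 1.5-fold apart the other way in a class where it had enough UMIs. Of the 20 genes 16 were higher and 4 lower, among them Ctse, Cdk5rap1, Camk2b, Slc15a2 and mt-Atp8. RNA from other cells stays open for all 20 genes. For 7 of them the gain or loss differed over 2-fold between classes both in CPM and in UMIs per cell, a test chosen after 2 earlier versions. It cannot decide, since a class that is the source of the RNA would itself differ more than the classes that receive it. A passenger segment around Vsig4 was argued against, with 0 genes within 10 Mb of Vsig4, and 0 belong to the cytotoxic list. Among 50 genes of a wider set, tried second, Ctse, Chil1, Ppfia4 and Rnpep lie within 5 Mb on chromosome 1, a number reached in 54 of 1000 random draws. Btg2, which is not in that set, lies between them and was higher in 13 of 14 classes and lower in 1. Strain background or library batch stays open with 1 library per genotype, and these genes may therefore mark the libraries and not the loss of Vsig4.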
